A study of Homo sapiens with 2 samples.

How the data were processed

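RNA was measured in 2 samples of BE(2)C, a human neuroblastoma cell line with amplified MYCN. One culture was transfected with small interfering RNA (siRNA) against MYCN, the other with control siRNA, and RNA was taken 36 hours after transfection. Per the labels' protocols, the transfection reagent was Lipofectamine 2000, 100 ng of RNA was labelled with the WT PLUS kit, and the samples were hybridised to Affymetrix Human Gene 2.0 ST arrays, 1-colour arrays that measure each transcript with several short probes (a probe set). The siRNAs of the 2 arms came from different suppliers, per the labels' protocols.

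The deposited table holds 1 log2 value per probe set and array, made by the authors with RMA, per the submitters' processing notes. RMA is a method that, as usually run, corrects the background, equalises the distributions of the arrays and summarises the probes of each probe set on the log2 scale; which of its settings were used is not given in the sources used here. The software, its version, and the other arrays normalized in the same run, if any, are not given in the sources used here. The values bear out a log2 scale without centring: they ranged from 0.85 to 13.5, the column medians were 4.6 (control siRNA) and 4.55 (MYCN siRNA), and the sorted values of the 2 columns lay within 0.128 of each other. With distributions this alike, a change in the total amount of messenger RNA per cell cannot be seen in these values. The title of the control array carries the word reanalysis, with no explanation in the sources used here.

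The table analysed here has 46255 rows. The platform annotation gave 15835 of them 1 gene symbol and none of them several, and left 30420 unnamed here. All 15835 gene identifiers matched the RefSeq gene table of GRCh38.p14, which was used for current symbols, gene types and the order of neighbouring genes only. These rows stood for 14812 genes, of which 651 had more than 1 probe set; the log2 values of a gene's probe sets were averaged. The level of MYCN itself was not analysed here.

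A gene counted as measured when it lay at or above the median of all rows in at least 1 array, which kept 10592 genes (71.5%), 9376 of them protein coding. The difference is the MYCN siRNA value minus the control siRNA value, and fold sizes are powers of 2 of it. With 1 array per group there is no replicate, no p-value is given, and the number of arrays limits the precision. The only spread that these data give is that between probe sets of 1 gene. In 374 measured protein-coding genes with at least 2 probe sets that did not hold identical values (21 further genes did), the differences of the first 2 probe sets gave an SD of 0.31 per probe set on the log2 scale, and 3.5% of the pairs lay 1 or more apart. Both probe sets of a pair read the same 2 RNA samples on the same 2 arrays. This SD therefore leaves out spread from labelling and hybridisation that they share, and the spread between cultures.

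Choices fixed before the data were examined were a threshold of 2-fold for counting genes, 42 gene lists, and the rule for named genes. That rule takes the 12 measured protein-coding genes with the largest difference in each direction and, of each list, the members with the highest and the lowest difference and up to 2 more in the direction of the list's median. MYCN was to be named too. Lists were compared by their median difference over measured members. Each median was placed among 10000 random lists of the same size drawn from the measured genes and matched on 10 bins of mean level. A list is called lower or higher when its median lay outside the central 95% of the random lists, which describes these 2 arrays and is no test across cultures. Of the 42 lists, 40 had at least 3 measured members. The replication-dependent histones and the ABC drug transporters are not reported here. Chance alone would put about 2 of 40 independent lists outside.

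The scripts were tested on simulated data drawn for the 10592 measured genes with the spread of the real differences at each level (scaled median absolute deviation). Of 200 genes shifted by 1.5 up or down on the log2 scale, 88.5% passed the 2-fold threshold, against 0.89% of unchanged genes. Of 100 simulated lists of 40 genes, 2 lay outside the central range of 1000 random lists without a shift, and 100 lay below it with a shift of −0.3. Simulated genes varied independently, and most lists below have fewer than 40 measured members, so these rates do not carry over to them. With 5 members, as for amino acid transport and glutamine use, a median of −0.3 lies inside the random range of −0.37 to 0.49. A list inside its range is therefore not shown to be unchanged. Alternatives were other normalizations of the deposited values (median centring, quantile, loess with a span of 0.3), the brightest probe set in place of the mean, no filter or a filter at the 70th percentile, a threshold of 1.5-fold, an offset of 16 on linear values, unmatched random lists, and lists without members of other lists. Random lists of protein-coding genes only were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.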

Results

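The study asked which transcripts differ when MYCN, the transcription factor whose gene is amplified in BE(2)C neuroblastoma cells, is targeted with siRNA. It set 1 array of cells given MYCN siRNA against 1 array of cells given control siRNA, both 36 hours after transfection. The arrays correlated at r = 0.986 over 46255 probe sets. The median difference of the 10592 measured genes was 0.01 and their SD was 0.43 on the log2 scale. No value below has a replicate. An SD of 0.31 per probe set, taken from genes measured by more than 1 probe set, is the only yardstick here for single genes. It leaves out spread between the arrays that the probe sets of a gene share, so it does not give the full technical spread. Values near the array medians of 4.6 and 4.55 are not shown to be above background. How far 2 cultures differ without MYCN siRNA was not measured. The level of MYCN itself was not analysed here, so the extent of its knockdown is not given.

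In the MYCN siRNA array, 234 measured genes were at least 2-fold higher and 123 at least 2-fold lower than in the control array. Of these, 200 and 109 were protein coding. The genes that were lower had a median mean level of 7.65, against 6.60 for the genes that were higher and 6.75 for all measured genes. When 16 was added to the linear values to damp dim genes, the count of higher genes was 124 and that of lower genes 87.

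Among the 12 protein-coding genes furthest below the control was LGR5, a receptor for R-spondins that marks stem cells, at 8.39 in the control array and 6.12 in the MYCN siRNA array (log2 difference −2.27, 4.82-fold lower). HK2, the hexokinase that starts glycolysis in many tumour cells, was 3.58-fold lower. CD320, the receptor for transcobalamin-bound vitamin B12, was 3.24-fold lower, and SV2A, a synaptic vesicle protein, was 3.21-fold lower. NOLC1, a nucleolar chaperone of small nucleolar ribonucleoproteins, went from 10.8 to 9.22 (2.92-fold lower). MRM1, a methyltransferase of mitochondrial ribosomal RNA, was 3.00-fold lower, and SFXN2, a mitochondrial sideroflexin, 2.97-fold lower. ERO1A, an oxidase of the endoplasmic reticulum, was 2.88-fold lower, and PMAIP1, which encodes the pro-apoptotic protein NOXA, 2.85-fold lower. NT5DC3 (3.52-fold), LIX1 (3.44-fold) and the metallothionein MT1X (3.09-fold) completed this group. MT1X belongs to a family of near-identical genes, so its value is uncertain. LIX1 was at 4.69 in the MYCN siRNA array, close to that array's median of 4.55, so its fold is uncertain.

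Among the 12 furthest above it, TP53INP1, a stress-response gene and p53 target, went from 5.36 to 8.08 (log2 difference 2.72, 6.58-fold higher). ZNF610, a zinc finger gene, was 5.04-fold higher and CLIP3, a cytoplasmic linker protein, was 5.01-fold higher. RRAS, a RAS-related GTPase, was 3.65-fold higher, RGS9, a regulator of G-protein signalling, 3.56-fold higher, and DYRK1B, a kinase associated with quiescence, 3.33-fold higher. CD68, a lysosomal membrane protein abundant in macrophages, was 3.33-fold higher. KLHDC8A (3.70-fold), CRISPLD2 (3.51-fold), KIAA0825 (3.49-fold), TP53TG3 (3.45-fold) and KLHDC1 (3.31-fold) were the others. TP53TG3 has near-identical copies, so its value is uncertain. ZNF610, KIAA0825 and KLHDC1 were below 5 in the control array, close to or under its median of 4.6 over all probe sets, so their folds are uncertain too.

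**Figure D1:**
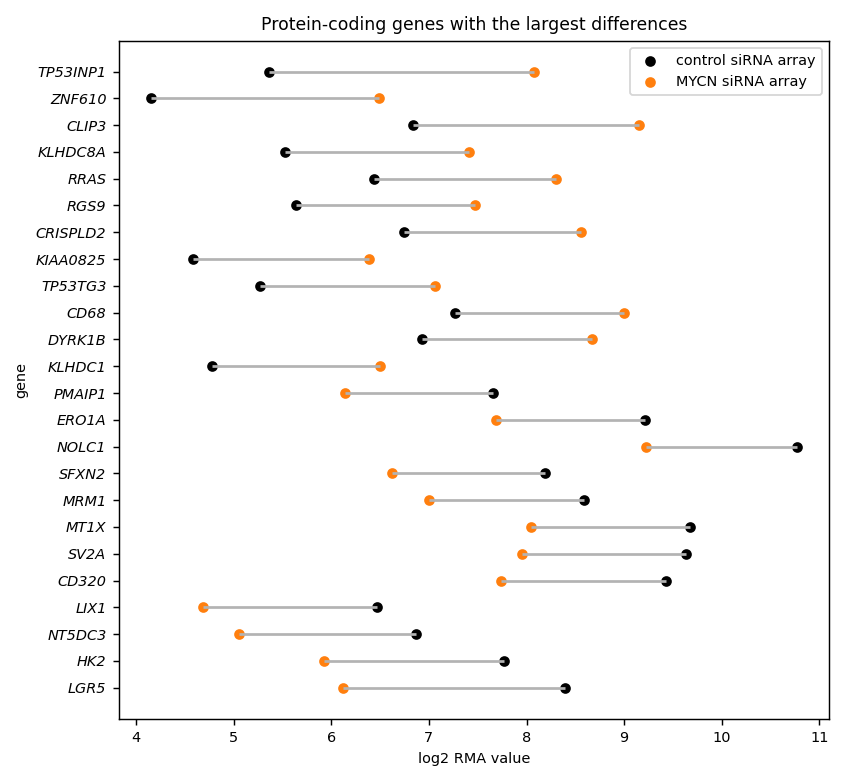
Log2 RMA value (x axis) of the 24 protein-coding genes with the largest differences (y axis), in the control siRNA array (black) and the MYCN siRNA array (orange), 1 array each, with a grey line joining the 2 values of a gene. TP53INP1 has the longest line toward higher values, from 5.36 to 8.08, and LGR5 the longest toward lower values, from 8.39 to 6.12.

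Of the 40 gene lists with measured members, 12 had a median below and 3 a median above the central 95% of matched random lists. Counts are of the measured members of each fixed list, not of every gene of its kind. The factors that make ribosomes were the list furthest from the random ones. Of its 45 measured members, 44 were lower and 10 of them at least 2-fold lower. The median difference was −0.63 (1.55-fold lower), below all 10000 random lists, whose central 95% ran from −0.10 to 0.15. NOLC1 was 2.92-fold lower, NOP16 2.57-fold lower and RRS1, a ribosome assembly factor, 2.40-fold lower. DDX52, an RNA helicase, was the only member that was not lower, at 0.06. The 7 measured members of the list of RNA polymerases I and III, which transcribe ribosomal and transfer RNA, were lower (median −0.36, random range −0.30 to 0.39). POLR3GL, a polymerase III subunit outside the list that was looked up after the values were seen, was at 0.46, and the 11 measured genes with POLR symbols, polymerase II subunits included, had a median of −0.24, inside their random range of −0.25 to 0.29. POLR3G, a polymerase III subunit, was 2.74-fold lower, POLR3E 2.31-fold lower and GTF3A, the 5S ribosomal RNA factor, 1.73-fold lower, while POLR1F was at −0.08.

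Structural proteins of the ribosome were lower by less. All 43 measured members of the cytosolic ribosomal protein list were lower (median −0.30, 1.23-fold, below all 10000 random lists), none by 2-fold in the values as deposited. RPS14 passed 2-fold narrowly after quantile normalization (−1.02) and loess (−1.01). Of the paralogs outside the list, looked up after the values were seen, RPL22L1 was at −1.08 and RPL39L at 0.26. RPS14 was lowest at −0.98, followed by RPL32 at −0.86 and RPL6 at −0.61, and RPS15A was nearest to 0 at −0.07. Ribosomal protein genes have many processed pseudogenes, so single values are uncertain. Of 64 mitochondrial ribosomal proteins, 46 were lower (median −0.14, random range −0.07 to 0.15), from MRPL42 at −0.69, MRPS2 at −0.59 and MRPL48 at −0.57 to MRPS31 at 0.22. Among 18 aminoacyl-tRNA synthetases and partners, 15 were lower (median −0.22, random range −0.18 to 0.19), led by VARS1, LARS1 and YARS1, the valyl-, leucyl- and tyrosyl-tRNA synthetases, at −0.49, −0.49 and −0.48, with SARS1 at 0.02. The 15 translation initiation and elongation factors had a median of −0.10, inside their random range of −0.20 to 0.23. EIF4EBP1, a repressor of cap-dependent translation, was at −0.83, EIF5A at −0.78, EIF4B at −0.66 and EEF1A2 at 0.40.

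Genes reported in the literature as MYC or MYCN targets had a median of −0.49 over 28 measured members (1.40-fold lower, below all 10000 random lists). Of these, 27 were lower. GRWD1, a ribosome and chromatin assembly factor, was 1.82-fold lower, and NOLC1 and RRS1 are members of this list too. LDHA, lactate dehydrogenase A, was the member that was not lower, at 0.33. Only 7 of the 28 stand in no other list, and these had a median of −0.43 (random range −0.30 to 0.38).

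Nucleotide synthesis was lower in 17 of 21 measured enzymes (median −0.35, 1.27-fold lower, random range −0.16 to 0.19). PFAS, an enzyme of purine synthesis, was 2.31-fold lower, IMPDH2, the rate-limiting enzyme of guanine nucleotide synthesis, 1.62-fold lower, and CTPS1, CTP synthase, 1.61-fold lower, with CTPS2 at 0.24. Serine, glycine and folate enzymes were lower in 11 of 15 (median −0.26, random range −0.21 to 0.24). GCSH, of the glycine cleavage system, was dim in both, at 4.81 in the control array and 3.67 in the MYCN siRNA array, MTHFD1L, a mitochondrial folate enzyme, was 1.87-fold lower and PSAT1, of serine synthesis, 1.73-fold lower, with PSPH at 0.30. Without members of other lists the median of this list was −0.18, inside the random range. Polyamine genes went both ways, with a median of −0.10 over 17 members (random range −0.19 to 0.21), which turned to 0.03 without members of other lists and was −0.03 after loess. The synthetic enzymes SRM, spermidine synthase, and ODC1, ornithine decarboxylase, were 1.81-fold and 1.77-fold lower from levels of 11.7 and 11.6, EIF5A was 1.72-fold lower, and AZIN2, an antizyme inhibitor, was at 4.46 in the control array, under its median of 4.6, and 5.22 in the MYCN siRNA array.

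The lists of energy and amino acid metabolism stayed inside their random ranges, but a minority of their genes was measured. These were 9 of 25 for glycolysis, 5 of 23 for amino acid transport and glutamine use, and 15 of 64 for the respiratory chain. Of the measured glycolysis genes 7 were lower and 2 higher, and of the amino acid genes 4 were lower and 1 higher. The pathways are therefore not shown to be unchanged. The 9 measured glycolysis genes had a median of −0.23 (random range −0.25 to 0.36), with HK2 at −1.84, PGAM1, phosphoglycerate mutase, at −0.74, TPI1 at −0.31 and LDHA at 0.33. The 5 genes of amino acid transport and glutamine use also had a median of −0.23 (random range −0.37 to 0.49), with PYCR1, a proline synthesis enzyme, at −1.10, GLUD1 at −0.57, ASNS at −0.23 and OAT at 0.06. The 15 respiratory chain subunits had a median of −0.01, from CYC1 at −0.28, UQCRC2 at −0.22 and COX5B at −0.14 to COX6A1 at 0.74, which was 0.11 with the brighter of its 2 probe sets. The 13 chaperones had a median of −0.21 (random range −0.22 to 0.21), with TRAP1, the mitochondrial HSP90, at −0.71, HSPH1 at −0.59, HSPD1 at −0.56 and HSPB1 at 0.39; after quantile normalization the median, −0.19, lay below its range.

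Splicing factors were lower in 24 of 30 (median −0.20, random range −0.13 to 0.16). PRPF4 was at −1.32, PRPF31 at −0.78 and PRPF3 at 0.28, and SNRPF was dim in both arrays, at 4.70 in the control array and 4.16 in the MYCN siRNA array. Nuclear transport genes were lower in 24 of 27 (median −0.22, random range −0.15 to 0.16). XPO5, the exporter of microRNA precursors, was 2.03-fold lower, IPO4, an importin, 1.94-fold lower and the nucleoporin NUP35 was at 5.66 in the control array and a dim 4.92 in the MYCN siRNA array, with TNPO1 at 0.16.

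**Figure D2:**
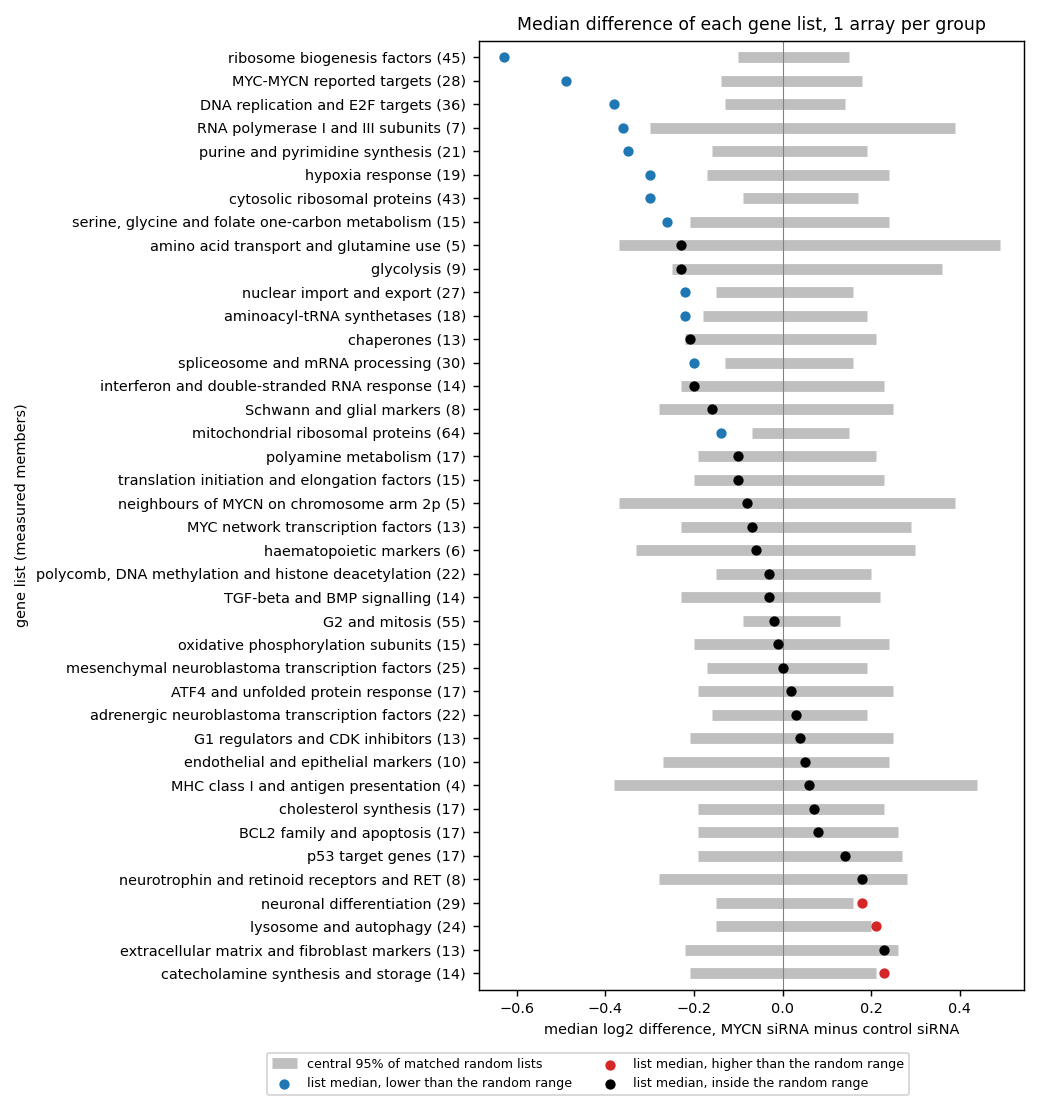
Median log2 difference, MYCN siRNA minus control siRNA (x axis), of 40 gene lists (y axis, number of measured members in parentheses). Grey bars span the central 95% of 10000 random lists matched on size and mean level; medians below it are blue (12 lists), above it red (3 lists) and inside it black (25 lists).

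DNA replication and E2F target genes were lower in 30 of 36 (median −0.38, 1.30-fold, below all 10000 random lists, random range −0.13 to 0.14), none of them by 2-fold. UHRF1, which recruits the maintenance DNA methyltransferase, was 1.98-fold lower, E2F8 1.85-fold lower and CCNE1, cyclin E1, 1.80-fold lower, while E2F7 was at 0.51. The 55 measured genes of G2 and mitosis had a median of −0.02 (random range −0.09 to 0.13), with 29 lower and 24 higher. CCNA2, cyclin A2, was 2.06-fold lower, CENPN 1.93-fold lower and CDC25A 1.44-fold lower, and CEP55 was at 0.48. The 13 G1 regulators had a median of 0.04 (random range −0.21 to 0.25), from CCNE1 at −0.85 to CDKN3 at 0.38, CCND3 at 0.30 and RB1 at 0.24.

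The p53 target list had a median of 0.14 over 17 members (random range −0.19 to 0.27), and its members went both ways. Without members of other lists its median was 0.38, above the range. TP53INP1 was 6.58-fold higher, TP53I3 2.24-fold higher and GDF15, a stress-induced cytokine, 2.02-fold higher, while PMAIP1 was 2.85-fold lower. The 17 BCL2 family and apoptosis genes had a median of 0.08 (random range −0.19 to 0.26), with APAF1, the apoptosome scaffold, at 0.83, BIRC2 at 0.74, XIAP at 0.56 and PMAIP1 at −1.51.

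Of 14 genes of catecholamine synthesis and storage, 13 were higher (median 0.23, 1.17-fold, random range −0.21 to 0.21). DBH, the enzyme that makes noradrenaline, went from 9.32 to 10.8 (2.73-fold higher), the secretory granule protein SCG5 was at a dim 4.36 in the control array and 5.25 in the MYCN siRNA array, CYB561, the granule cytochrome, was 1.70-fold higher, and PNMT was at −0.16. Against random lists not matched on level this median lay inside the range. Of 29 neuronal differentiation genes, 19 were higher (median 0.18, 1.13-fold, random range −0.15 to 0.16). DCX, doublecortin, was 1.87-fold higher, NRXN2 1.78-fold higher and STMN4 1.72-fold higher, and DPYSL3, a growth cone protein, was 1.77-fold lower. The 8 neurotrophin, retinoid and RET receptors had a median of 0.18 (random range −0.28 to 0.28), with RET at 0.91, STRA6 at 0.61, ALK at 0.35 and NGFR at −0.46. The 22 adrenergic transcription factors had a median of 0.03 (random range −0.16 to 0.19). LIN28B, an RNA-binding inhibitor of let-7 microRNAs that was placed in this list, was 2.49-fold lower, and KLF13, GATA2 and EYA1 were at 0.28, 0.23 and 0.22.

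Lysosome and autophagy genes were higher in 21 of 24 (median 0.21, 1.15-fold, random range −0.15 to 0.20). GRN, progranulin, was 1.69-fold higher, CD63 1.59-fold higher and LAMP2, a lysosomal membrane protein, 1.57-fold higher, while TPP1, a lysosomal peptidase, was 2.66-fold lower. With a filter at the 70th percentile this median, 0.22, lay inside the random range. The hypoxia list had a median of −0.30 over 19 members (random range −0.17 to 0.24), 11 lower and 8 higher. HK2 (−1.84), ERO1A (−1.52) and STC2 (−0.95) were its lowest members and BNIP3L, a mitophagy receptor, its highest at 0.66. Its median without members of other lists was 0.02, so this list's place rested on genes it shares with others.

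**Figure D3:**
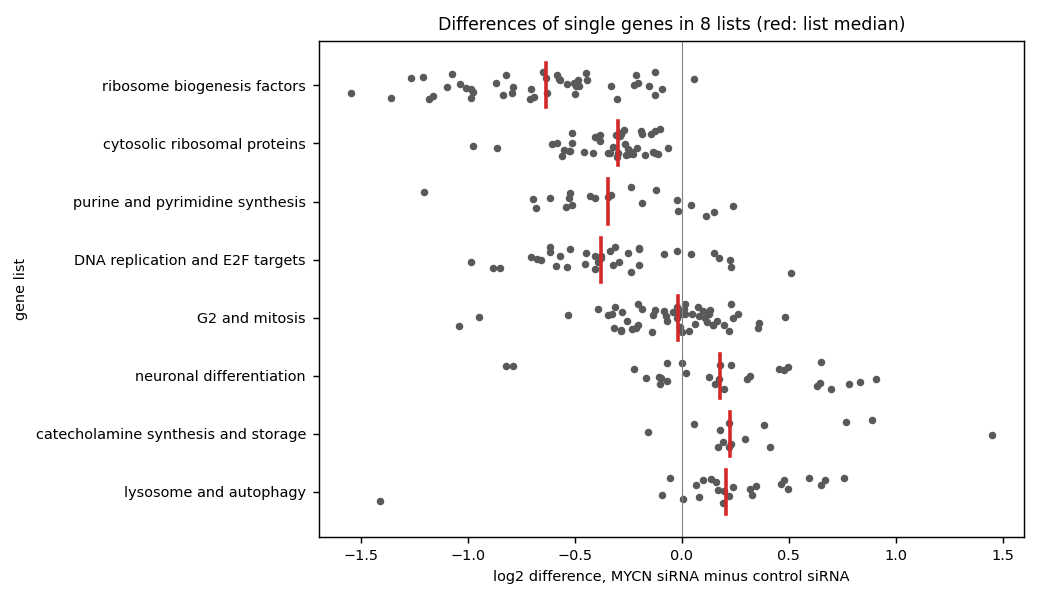
Log2 difference, MYCN siRNA minus control siRNA (x axis), of each measured gene (grey points) in 8 lists (y axis); red lines mark the list medians and the vertical scatter within a list carries no meaning. Ribosome biogenesis factors lie almost entirely below 0 (median −0.63), genes of G2 and mitosis lie around it (median −0.02), and the 3 lists at the bottom have medians above it (0.18, 0.23 and 0.21) with members on both sides.

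Markers of other cell states and cell types gave no list outside the random range as planned, with exceptions under alternatives given beside them. The 25 mesenchymal neuroblastoma factors had a median of 0.00 (SIX4 −0.70, VIM 0.57), and MAML2 was at a dim 4.53 in the control array and 5.33 in the MYCN siRNA array, its difference of 0.80 being 0.49 with the brighter of its 2 probe sets. The 13 matrix and fibroblast genes had a median of 0.23, just inside their range of −0.22 to 0.26, with TIMP3, a metalloproteinase inhibitor, at 1.32 and LUM, lumican, at −1.17; the median was above the range after loess (0.29) and after quantile normalization (0.28), and 0.14, well inside, with the 70th percentile filter. The 8 Schwann and glial genes had a median of −0.16 (S100B 1.02, NGFR −0.46, SOX10 −0.28), which turned to 0.70, above the range, when only genes past the 70th percentile filter were kept. The 6 haematopoietic genes had a median of −0.06 (CD68 1.74, CSF1R −0.38) and the 10 endothelial and epithelial genes one of 0.05 (CLDN4 0.99, KDR −0.65). CD68 lay at 7.27 in the control array, CSF1R at 4.64, CLDN4 at 4.61 and KDR at 4.64, the last 3 close to the array median.

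The remaining lists also lay inside their random ranges. The 14 interferon and foreign-RNA response genes had a median of −0.20 (random range −0.23 to 0.23), with IRF1 at −0.40, DHX58 at −0.40, OASL at −0.35 and IFI35 at 0.75. Both cultures were transfected, so a response to transfection shared by both would not show in this difference. The 4 class I antigen presentation genes had a median of 0.06 (TAPBP 0.43, B2M −0.04), and B2M was at 0.18 with the brighter of its 2 probe sets. The 17 ATF4 and unfolded protein response genes had a median of 0.02 (STC2 −0.95, DDIT4 0.82, VLDLR 0.69), or 0.29, above the range, without members of other lists. The 17 cholesterol synthesis genes had a median of 0.07 (MVD −0.42, TM7SF2 0.61). The 14 TGF-beta and BMP genes had a median of −0.03 (SMAD7 0.57, TGIF1 −0.34). The 22 polycomb, DNA methylation and deacetylase genes also had a median of −0.03 (UHRF1 −0.99, DNMT3A 0.50). The 13 MYC network factors had a median of −0.07 (random range −0.23 to 0.29), or −0.27, below it, with the brightest probe set of each gene. MLX was at −0.70, MLXIPL at a dim 5.01 in the control array and 4.42 in the MYCN siRNA array, MNT at −0.45 and MXD4, a MAX-binding repressor, at 0.66. Of the genes that lie near MYCN, 5 were measured (median −0.08, random range −0.37 to 0.39), and with the brightest probe set of each gene the median turned to 0.12, inside the range too. DDX1 and NBAS, often co-amplified with MYCN, were at −0.18 and 0.13, TRIB2 at −0.08 and GEN1 at −0.41. TRIB2 was at 0.18 with the brighter of its 2 probe sets. Of the genes named in these lists, RPL32, GCSH, AZIN2, MLXIPL, PNMT, SCG5, SIX4, MAML2, CSF1R, KDR, CLDN4, IRF1, DHX58, OASL, SNRPF, NUP35 and POLR3GL lay below 5 in at least 1 array, so their differences are uncertain.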

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

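The unnamed probe sets were counted after the named genes had been seen. Of 12942 unnamed rows at or above the median in at least 1 array, 272 (2.10%) were at least 2-fold higher and 229 (1.77%) at least 2-fold lower in the MYCN siRNA array, against 2.21% and 1.16% of the measured named genes. They drew attention because none of the comparisons above uses them. The lowest differences were those of probe sets 16722401, at 5.18 in the control array and 1.76 in the MYCN siRNA array, and 17104671, at 5.27 and 1.90. The highest were those of 17017216, at 2.26 and 4.84, and 16670183, at 3.07 and 5.50. In each of these 4 the lower value lay far under its array's median of 4.6 or 4.55 and was not shown to be above background, so no fold is given.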

How the results depend on the processing

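Random lists of protein-coding genes only were chosen after the data were seen, and left all 40 lists where they were. Of 15 lists outside the central 95%, 11 stayed outside on the same side under every alternative run; the exceptions are serine, glycine and folate metabolism, catecholamine synthesis, lysosome and autophagy, and hypoxia. Without members of other lists, the hypoxia median turned from −0.30 to 0.0249 and the serine, glycine and folate median went to −0.18, inside the range, while p53 targets (0.38) and the ATF4 and unfolded protein response (0.29) came to lie above it. Against unmatched random lists, catecholamine synthesis (0.23) lay inside. With the filter at the 70th percentile, lysosome and autophagy (0.22) lay inside and Schwann and glial markers (0.70) above. Quantile normalization put chaperones (−0.19) below and matrix and fibroblast genes (0.28) above the range; loess did the latter too (0.29). With the brightest probe set, MYC network factors (−0.27) lay below. Some medians near 0 crossed it under at least 1 alternative while staying inside the range: those of polyamine metabolism, respiratory chain subunits, G2 and mitosis, G1 regulators, adrenergic factors, haematopoietic markers, TGF-beta and BMP signalling, polycomb and DNA methylation, and the neighbours of MYCN. The ATF4 median also crossed 0 with quantile normalization and the 70th percentile filter. No direction is read from these lists. The matrix and fibroblast median was 0.14 with the 70th percentile filter. The cause was not tested for any of these, and 2 lists kept too few members for the 70th percentile filter. A 1.5-fold threshold counted 933 genes higher and 613 lower. The offset of 16 counted 124 higher, all among the 234, which follows from its shrinking of dim genes. All other alternatives left the counts within 1.5 times, at 192 to 249 genes higher and, the offset included, 87 to 138 lower. Of 42 named genes beyond 2-fold, 38 stayed so under each normalization and with the brightest probe set; CCNA2, GDF15, S100B and XPO5 ended just under it, and none changed direction. RPS14, STC2 and CLDN4, just under 2-fold as deposited, passed it after quantile normalization (−1.02, −1.0032 and 1.03), and RPS14 and CLDN4 also after loess (−1.01 and 1.06). No alternative could be run for MYCN itself, whose level was not analysed. Dim genes have the least signal over background: among the dimmest 2119 measured genes, with a median level of 4.89, 41 were higher and 12 lower.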

Other observations

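The scan of gene families, the comparison of replication with mitosis genes, that of the genes next to the protocadherin cluster and the question of a difference between cultures were chosen only after the results were seen. Families were taken as genes sharing a symbol stem, pseudogenes included. Of 175 stems with at least 8 measured members, 16 had a median below and 14 a median above the central 95% of 2000 matched random lists, where chance would give about 8.8 in all. Only some of these families are described, without a fixed rule for the choice. Among the others, genes with SYT symbols were lower in 12 of 16 (median −0.25, random range −0.23 to 0.18). Genes with MCM symbols were lower in 11 of 11 (median −0.49), and those with TP symbols higher in 8 of 10 (median 0.57). The protocadherin beta genes, neural cell adhesion proteins encoded in a cluster, were higher in 17 of 17 (median 0.78, random range −0.18 to 0.25). The 17 include 2 pseudogenes. PCDHB7 was 3.14-fold higher, PCDHB5 2.77-fold, PCDHB15 2.18-fold and PCDHB8 2.04-fold, and PCDHB3 was lowest at 0.29. PCDHB5 was at 4.15 in the control array, under its median of 4.6, so its fold is uncertain. Zinc finger genes with ZNF symbols were higher in 294 of 426 (median 0.20, random range −0.02 to 0.06), 17 of them at least 2-fold and none 2-fold lower. Intraflagellar transport genes, which build cilia, were higher in 15 of 17 (median 0.35, random range −0.18 to 0.27), with IFT80 1.91-fold higher. Sorting nexins of the endosome were higher in 22 of 26 (median 0.31, random range −0.16 to 0.18), with SNX16 1.79-fold higher.

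Mitochondrial protein import genes were lower. Of 13 TIMM genes, named for the translocase of the inner membrane, 11 were lower (median −0.28, random range −0.21 to 0.27), with TIMM50 1.87-fold lower, and of 9 TOMM genes, named for that of the outer membrane, 8 were lower (median −0.35, random range −0.27 to 0.29), with TOMM34 1.82-fold lower. Host genes of small nucleolar RNAs were lower in 7 of 8 (median −0.51, random range −0.26 to 0.36), led by SNHG15 (2.58-fold) and SNHG8 (2.54-fold). Genes with MIR symbols, microRNAs and some of their host genes, went both ways: their median was −0.12 over 354 members (random range −0.06 to 0.03), with 220 lower and 131 higher, but 15 were at least 2-fold higher and 6 at least 2-fold lower. Whether these probe sets lay above background, or read microRNAs and not longer transcripts, was not tested. Their values are therefore not read as changes in microRNA levels. The median of each family named here stayed on its side of the random range after median centring, quantile normalization and loess. The SYT, MCM and TP genes were not part of that check.

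The lower level of ribosome biogenesis genes was not removed by taking out the dependence of the difference on brightness: after loess the median was −0.66, against a random range of −0.10 to 0.16, so an intensity-dependent bias does not account for it. The 7 reported MYC targets that stand in no other list had a median of −0.43, below their random range of −0.30 to 0.38. They are not wholly separate from the ribosome genes. Their 2 lowest members were GRWD1 (−0.86), a ribosome and chromatin assembly factor, and RIOX2 (−0.81), a ribosomal oxygenase. The low median of the 7 targets goes with the hypothesis of a lower level of MYC-activated genes after MYCN siRNA but rests on 7 genes. A difference between the 2 cultures or arrays unrelated to the siRNA, or an effect of this siRNA on other transcripts, cannot be told apart from it with 1 array per group.

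Replication genes were lower while mitosis genes were near 0. The medians differed by −0.36 (random pairs −0.18 to 0.17). Bootstrap intervals over genes were −0.46 to −0.25 for replication and −0.08 to 0.03 for mitosis, and did not overlap. They describe the genes of this pair of arrays and not the spread between cultures. Both medians had been seen before this comparison, so it restates the pattern and is no separate evidence on its cause. A smaller share of dividing cells that lowers both lists by about as much would need a lower mitosis median. That median was −0.02, with 29 genes lower and 24 higher, so the 2 lists did not fall alike. Whether fewer dividing cells would lower both lists alike was not tested, so these values do not decide on a smaller share of dividing cells. After loess the difference was −0.357, a run that could change little, as above. The brightness trend was too small to account for the gap. A shift of cells between phases and a lower level of replication genes per cell stay open and were not tested. So do a smaller share of dividing cells with unequal effects on the 2 lists, and a difference between cultures.

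The protocadherin beta genes kept a median of 0.78 after loess (random range −0.18 to 0.26), a run that could change little, as above. The brightness trend was too small to account for that median. The 20 nearest measured genes that are not protocadherins, 10 on each side, had a median of 0.02 (random range −0.17 to 0.23). Of these, 11 were higher and none by 2-fold, which argues against a change that reaches the genes around the protocadherins. Protocadherins other than the beta genes were left out of this comparison. It therefore cannot decide on a change shared by the protocadherin genes of the region. How far the probe sets of these similar genes share targets was not tested, nor was any link to MYCN, and a difference between the 2 cultures stays open.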
